A study of Mus musculus with 4 samples.

How the data were processed

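Gene expression was measured in cerebral cortex RNA of adult female mice exposed to nicotine or saccharin through the dam and then until weaning. Per the labels' protocols, RNA was isolated with a phenol reagent and a spin column, RNA of 4 animals was pooled, and 5 pools per experimental group are stated, together with 20 subjects in total. These numbers leave open whether the 20 subjects are those of each group. Biotin-labelled RNA made from the pools was hybridised to Affymetrix arrays. Values of 4 arrays were used here. Nothing states whether the 2 arrays of a title hold separate pools, so p-values measure only the spread between these arrays, which may be technical.

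Each array was assigned to a group and given a number by its title. The source name of every array states the exposure that its title does not, and nothing else in the labels decides between them. The groups are those of the titles, and every direction is stated by title. If the source names are right, every sign is to be turned.

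The array values are log2 expression values per probe set as the authors deposited them, and they were taken without further scaling in the main comparison. The scale was read from the values, which reach 16.6 with similar medians and a common lowest value, while the background correction, normalization and summary method are not given in the sources used here. In the authors' deposited table of comparisons the fold changes and mean levels are log2 values, per the file headers. Its p-value columns hold the authors' moderated p and its adjusted value, and its moderated statistic and log odds are a score per probe set from the authors' fit, per the file headers. limma is named in the submitters' processing notes without a version. Which group was subtracted in the authors' deposited table, and the number of arrays behind it, are not given in the sources used here. No column of per-sample values was left unused, and no filter on level was applied in the main comparison. Values near the lowest one carry no signal above background: 14459 probe sets were below 2.2 on all 4 arrays.

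Gene symbols came from the authors' deposited table, since it pairs probe sets with names. Of the 45101 probe sets, 6778 had no usable symbol, 58 of them because a spreadsheet had turned the symbol into a date. Among the 38323 named ones, 35358 matched a current RefSeq symbol or an older name in the annotation of mouse assembly GRCm38.p6, 3214 of them under an updated symbol, and 2965 kept the name in the table. No coordinates are given, because no genome build belongs to these values.

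The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 values of all 4 arrays, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The fit gave 0.320 prior and 2.32 total degrees of freedom. Gene lists, 16 of pathways and complexes and 12 of cell type and sex markers, were fixed before the data were examined, as were the named genes and the alternatives except those said to have been added. The 28 lists were tested with camera at a preset inter-gene correlation of 0.01, on the probe set with the highest mean for each gene, and adjusted over the 28 lists. No call held with an estimated correlation, a setting that also called 0 of 10 shifted lists in the simulated data below. Several genes stand in more than one list, such as Mef2c, Calb1 and Gjb6.

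The genes named in the text follow a rule in 4 parts. The first takes, among probe sets of 1 gene with a mean at or above the median of all probe sets, the 12 largest higher and 12 largest lower differences past the threshold, filled by order of p where fewer pass. Because none passed, all 24 came by order of p. The second part takes Ash2l and Mef2c, for which the study is known, and Chrna4, Chrnb2, Chrna7 and Chrna5. The third takes up to 4 members of each list with the smallest p at or above the median level, and the fourth every sex-specific gene. Some genes that the rule selects are not reported. Tut4, Cflar, Ntrk2, Trem2 and Actb, and the activity and stress genes Fos, Egr2 and Fkbp5, were chosen after their values were seen.

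Numbers 1 and 2 are not explained in the labels. Because the values split by number, with a correlation of 0.857 between the shifts of the 2 titles, number was treated as a batch seen in the data, and differences within each number and the fit with the number as a block are given beside the pooled ones where they change a call. The main fit has no block, so its SEs take in the shift between the numbers. Alternatives were quantile normalization, centring each array on its median, a filter on probe sets below the median level, the trend and robust variance model, the number as a block, 1 probe set per gene, a minimum difference of 0.5, the adjusted p of the authors' deposited table, an estimated correlation, fry, the mean of all probe sets of a gene, other probe sets of a gene and leaving out each array. The block with the filter, the block with the filter, trend and robust model, and camera on the statistics of the authors' deposited table were added after seeing the data. With an array left out the fit had no block, and 1 group kept only 1 of the numbers. Part of the shift between the numbers therefore enters the differences of such fits. A pseudocount was not needed, since the values were already on a log scale.

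The steps were tested on simulated data for the comparison of titled nicotine with titled saccharin, with the observed means and numbers over all 45101 probe sets. The spread was the observed one within numbers, smoothed over probe sets of similar level, and noise was drawn independently for each probe set. With 200 probe sets changed, 0 were recovered at 1.5-, 2- or 4-fold with or without the block, while the median estimates were 0.586, 1.00 and 2.01 on the log2 scale. With the spread scaled to 0.02 of the observed one, the fit with the block recovered 83.1%, 96.8% and 100% of them and the fit without it 0.3%, 0.4% and 4.5%. A count near 0 at the observed spread therefore leaves changes of these sizes open. For the lists, a shift of 0.15 in the myelin genes was called in 8 of 10 runs by camera without the block and in 10 of 10 with it, and in 0 of 10 with an estimated correlation, even at a shift of 0.5. These runs hold no correlation between genes, so they do not show how camera treats lists whose genes vary together. The precision of each value is limited by the number of arrays.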

Results

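The series measured messenger RNA in the cerebral cortex of adult female C57BL/6J mice, a common inbred laboratory strain. Dams received drinking solution with nicotine or with saccharin, the sweetener given alone to control dams, from conception. Exposure of the offspring ended at postnatal day 21, and they were left undisturbed to an age of 90 days. The question the design names is whether nicotine during development leaves a difference in cortical gene expression in the adult after a nicotine-free interval. RNA pooled from 4 animals was labelled with biotin and hybridised to Affymetrix arrays, and 4 arrays were analysed here. The titles put 2 arrays in each exposure group and number them 1 and 2. The title and the source name of every array state opposite exposures. The groups below are therefore called titled nicotine and titled saccharin, each difference is titled nicotine minus titled saccharin, and the opposite assignment stays open for every direction. The 45101 probe sets named 20737 genes. Array medians lay between 3.88 and 4.09 on the log2 scale, and up to 25.3% of the probe sets of an array held its lowest value. The number of arrays limits the precision of every value.

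Oligodendrocyte and microglia markers were higher as groups in the arrays titled nicotine in the main test, the only 2 of the 28 fixed lists that passed it. The microglia call was lost with the array number as a block (camera adjusted p = 0.0704). With 1 array left out neither call held throughout, and the medians ranged from 0.058 to 0.17 for myelin and from -0.053 to 0.26 for microglia. Both calls were lost with an estimated correlation between genes (adjusted p = 0.983). That loss tells little, since the same setting called 0 of 10 shifted lists in simulated data. Ash2l, Mef2c and the nicotinic receptor genes did not pass. Arrays resembled each other by their number more than by their title. No named gene passed the test between the exposures. One feature did, a probe set without a gene name, singled out after its values were seen: it stood at 3.48 on both arrays titled nicotine and at 4.11 on both titled saccharin, a difference of -0.63 (SE 0.00122, n = 2 per group, adjusted p = 0.0286 in limma). The mean of this probe set over the 4 arrays, 3.80, is below the median of all probe sets, 4.04. The direction of this and later values runs against the authors' deposited table, whose fold changes correlated with the differences by title at r = -0.871 across probe sets, although single genes such as Tm9sf3 have the same sign in both. At an unadjusted p under 0.05, 347 probe sets were counted, 100 higher and 247 lower in titled nicotine, against the 2255 that make up 0.05 of all probe sets. With the array number as a block, limma called 0 probe sets (2217 at an unadjusted p under 0.05). Among probe sets at or above the median level, 382 differed by more than 2-fold, and in 103 of these the groups did not overlap. Groups did not overlap in 9.31% of the probe sets at that level, against 33.3% for 4 exchangeable arrays, which these, close within a number, are not. An exact two-sided permutation of 4 arrays cannot give a p below 0.333.

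Of the genes chosen by rank, 23 are given as values, since each had an adjusted p of 1 in limma. The difference with the smallest p on the higher side was that of Tm9sf3, at 12.95 ± 0.000442 in titled nicotine and 12.88 ± 0.00127 in titled saccharin (mean ± SD, n = 2 each), a difference of 0.069. Gnptab, whose product starts the mannose tagging of lysosomal enzymes, differed by 0.15. The difference was 0.15 for the sorting nexin Snx5, 0.079 for Pcyt1b, 0.33 for Fgd4, 0.10 for Pdlim7 and 0.19 for the DNA repair gene Fancd2. It was 0.058 for Ubr4, 0.30 for Wdr37, 0.092 for the antioxidant enzyme gene Prdx1 and 0.50 for the phosphatase gene Ptpn12.

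On the lower side, Ccdc87 stood at 4.54 ± 0.00936 in titled nicotine and 5.14 ± 0.00890 in titled saccharin, a difference of -0.60 (SE 0.00856). Dtwd2 differed by -0.76, Dhx34 by -0.38, Aar2 by -0.36, the thrombospondin gene Thbs2 by -0.24 and Eif4e, which encodes the cap-binding translation factor, by -0.23. The difference was -0.16 for the kinase gene Dclk3, -0.15 for the clathrin adaptor gene Ap2a2, -0.14 for Slc46a3, -0.13 for Ica1, -0.046 for Mrfap1 and -0.045 for Slc43a2. Those of Mrfap1 and Slc43a2 turned positive when each array was centred on its median. A second probe set at or above the median level had the opposite sign for 7 of these 23 genes, Fgd4, Wdr37, Ptpn12, Ica1, Eif4e, Dtwd2 and Aar2.

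Ash2l and Mef2c, the genes for which the study is known, are a core subunit of the complexes that methylate histone H3 at lysine 4 and a transcription factor of neuronal activity and differentiation. The brighter Ash2l probe set stood at 9.39 ± 0.25 in titled nicotine and 9.36 ± 0.099 in titled saccharin, a difference of 0.029 (SE 0.177, n = 2 each, adjusted p = 1). The dimmer one read 4.43 and 4.49 on the arrays titled nicotine and 4.69 and 5.08 on those titled saccharin, a difference of -0.43 (SE 0.180, adjusted p = 1). In the authors' deposited table this dimmer probe set had a log2 fold change of 0.67 with an adjusted p of 0.00141, and the brighter one -0.024 with an adjusted p of 1. Mef2c at its brightest probe set was 14.62 ± 0.118 against 14.78 ± 0.0953, a difference of -0.17 (SE 0.0996, adjusted p = 1) that was -0.18 within number 1 and -0.15 within number 2. With the number as a block the SE of this probe set was 0.0140 (limma adjusted p = 0.814). The authors' deposited table gave 0.11 for it, with an adjusted p of 1. The 23 measured members of the H3K4 methyltransferase complexes had a median difference of -0.0078 and a mean of -0.024. For this list camera, which compares a list with all other genes, gave the opposite sign and an adjusted p of 0.985. Cxxc1 differed by -0.17 and Ncoa6 by -0.21, and neither they nor any other member passed. Over 34 other chromatin modifiers the median was -0.032 (adjusted p = 0.587), with Tet1 at -0.38 and Smarca4 at -0.12.

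Nicotinic receptor subunits, the targets of nicotine, had a median difference of 0 over 15 measured members (camera adjusted p = 0.967), and only 3 of them reached the median level. Chrna4 differed by -0.0093 (SE 0.0190), Chrnb2 by 0.094 (SE 0.191), Chrna7 by -0.12 (SE 0.205) and Chrna5, close to the median level, by 0.24 (SE 0.498), all with an adjusted p of 1. The small SE of Chrna4 in this fit without the block belongs to that probe set, at a mean level of 7.37. Another at 7.21 differed by -0.14 (SE 0.901), and another at 3.91, below the median level, by 0.55 (SE 0.883). The SE of 0.901 takes in the shift between the numbers. The probe set at 7.21 was at -0.12 within number 1 and -0.15 within number 2. With the number as a block its SE was 0.0136 (limma adjusted p = 0.873). Within numbers 1 and 2 the values were 0.33 and -0.14 for Chrnb2 and -0.52 and 0.99 for Chrna5, so for these genes the arrays did not give one direction. They gave one for Chrna7, -0.115 and -0.122, with an SE of 0.00306 and an adjusted p of 0.516 with the number as a block. The brightest Chrna4 probe set turned positive under quantile normalization and under centring. The other cholinergic genes had a median of 0.0052 over 13 members (adjusted p = 0.365), with Bche at 0.36 and Ric3, a chaperone of nicotinic receptors, at 0.17. Genes of nicotine metabolism and the xenobiotic response had a median of 0 over 17 members (adjusted p = 0.780), with Fmo1 at -0.33 and Nqo1 at -0.27. Over the 10 that reached the median level the median was -0.089. Monoamine receptors and signalling genes also had a median of 0 over 30 members, with a mean of -0.011 and a camera direction that was positive (adjusted p = 0.967), with Adra2a at -0.40 and Htr1f at 0.20. Their median was -0.081 over the 17 that reached the median level.

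Of the synaptic groups, none passed camera in the main test. Glutamate receptors and postsynaptic scaffold genes had a median of -0.059 over 42 members (adjusted p = 0.281), -0.044 within number 1 and -0.077 within number 2, and 21 were lower in titled nicotine in both numbers against 3 higher in both. Over all genes at or above the median level the medians were -0.010 within number 1 and -0.040 within number 2. Of those outside the myelin list, 16.8% were higher in both numbers. Of all 12206 genes at that level, 3309 were higher in number 1 and lower in number 2, and 2668 the reverse. The remaining genes, lower in both or without a difference in a number, outnumber those higher in both. Their exact share was not worked out, so such counts alone do not set a list apart. With centred arrays the glutamate median was -0.0057. With the number as a block the list passed (adjusted p = 0.00356), but not with the block and the filter on dim probe sets (adjusted p = 0.287) or the block and an estimated correlation (adjusted p = 0.929). An estimated correlation called 0 of 10 shifted lists in simulated data, so its losses for the lists here tell little alone. Grm5 differed by -0.19 and Grin3a by -0.17. Axon guidance ligands and receptors had a median of -0.060 over 36 members (adjusted p = 0.0913, or 0.0314 with the block), with 17 lower and 6 higher in both numbers, Plxnd1 at -0.12 and Efna5 at -0.10. The values over all genes given above apply to these counts too, and with centred arrays the median was -0.0066. The call with the block was lost with the filter added (adjusted p = 0.287) and with an estimated correlation (adjusted p = 0.929), and without the block the list passed when arrays were centred (adjusted p = 0.0156) and without titled nicotine 1 (adjusted p = 0.0293). Without titled nicotine 2 its median was 0.048. The median was 0.0053 over 20 GABA genes, whose mean was -0.016 (adjusted p = 0.780), and -0.039 over 34 genes of vesicles and release (adjusted p = 0.587), with Nrxn3 at -0.062 and Sv2b at -0.076. The vesicle list passed without titled nicotine 2 (adjusted p = 0.0286). Over 41 genes of dendrites and spines it was -0.0020 (adjusted p = 0.967), with Srgap3 at -0.040 and Map2 at -0.027.

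MEF2 family and activity-dependent genes had a median of -0.14 over 32 members (camera adjusted p = 0.142), but of 0.30 within number 1 and -0.62 within number 2. The list passed when arrays were centred (adjusted p = 0.000769). Its median was -0.37 without titled nicotine 1, 0.084 without titled nicotine 2, -0.15 without titled saccharin 1 and -0.055 without titled saccharin 2. Mef2c, above, and Rgs2, at -0.12, had the smallest p among its members. Glucocorticoid-responsive genes had a median of 0.0073 over 20 members (adjusted p = 0.310), 0.29 within number 1 and -0.16 within number 2, with Cdkn1a at 0.57 and Gjb6 at 0.21. The list's median was -0.29 without titled nicotine 1 and 0.39 without titled nicotine 2. Each of these fits takes in part of the shift from number 1 to number 2, whose median in this list was -0.38. Heat shock and unfolded protein response genes had a median of 0.063 over 27 members (adjusted p = 0.0913, or 0.0144 with the block), 0.15 within number 1 and -0.052 within number 2. The list also passed with the filter (adjusted p = 0.00816), the mean of all probe sets of a gene (adjusted p = 0.00746) and centred arrays (adjusted p = 0.0193). It did not pass with the block and an estimated correlation (adjusted p = 0.929), a setting that called 0 of 10 shifted lists in simulated data. Its median was -0.065 without titled nicotine 1, 0.20 without titled nicotine 2, 0.12 without titled saccharin 1 and -0.017 without titled saccharin 2. Of the heat shock genes, Hsp90b1 differed by 0.093 and Hsp90ab1 by -0.068. Oxidative phosphorylation had a median of -0.0021 over 46 members, with a mean of 0.011 and a positive camera direction (adjusted p = 0.967), with Sdha at -0.053 and Atp5c1 at 0.060, and cytosolic ribosomal proteins -0.011 over 46 (adjusted p = 0.167), with Rpl38 at -0.060 and Rpl15 at -0.053. The ribosomal list passed with the mean of all probe sets of a gene (adjusted p = 0.0466) and without titled saccharin 1 (adjusted p = 0.00278).

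**Figure D1:**
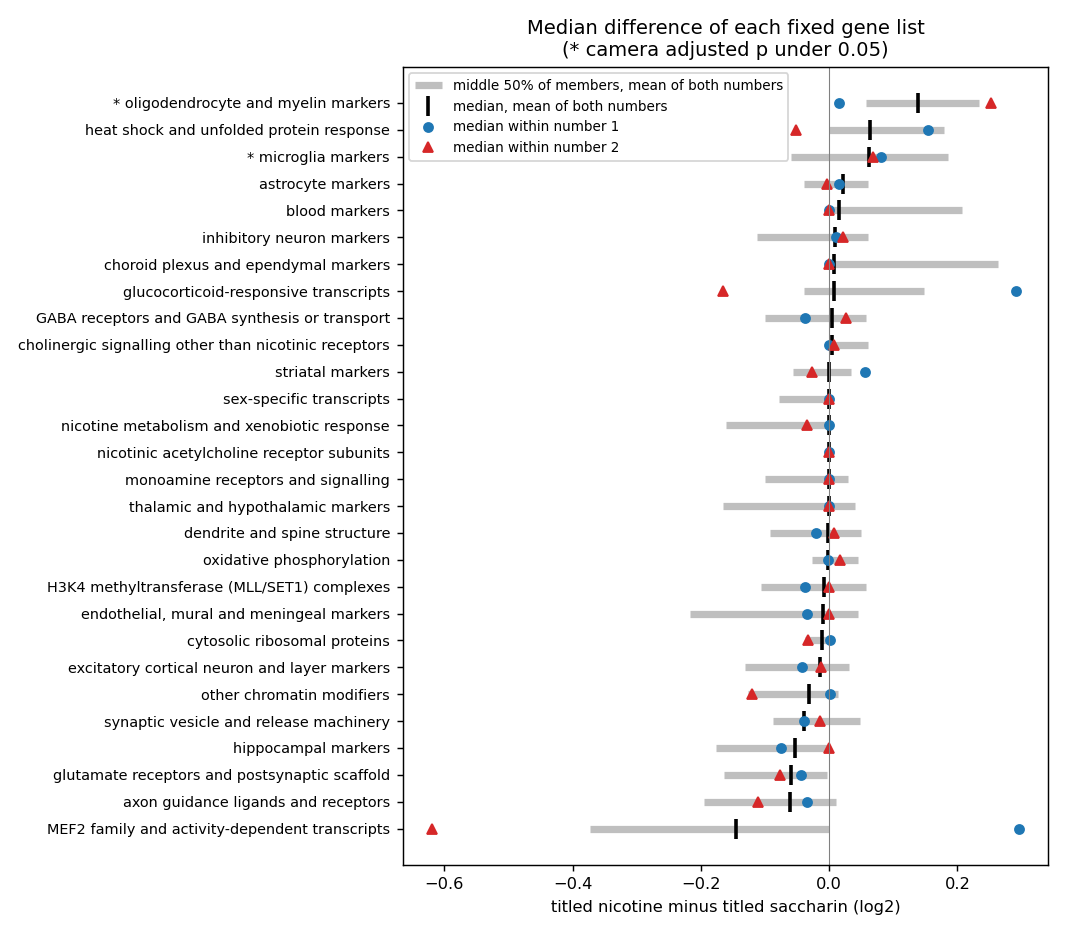
Median log2 difference, titled nicotine minus titled saccharin, of each of the 28 fixed gene lists (black bars, with the middle 50% of members in grey) and the medians within number 1 (blue circles) and number 2 (red triangles). The oligodendrocyte and myelin list lies highest at 0.14, and the activity-dependent list has its medians of 0.30 and -0.62 on opposite sides of 0. Centring the arrays adds 0.054 to every difference, which turns 9 small negative medians positive.

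Oligodendrocyte and myelin markers stood higher in titled nicotine as a group, with a median difference of 0.14 and a mean of 0.14 over 26 measured members (camera adjusted p = 4.81e-05, or 0.000886 with the block). In 13 members the array titled nicotine was higher in both numbers, and in 1 it was lower in both. Of 12180 other genes at or above the median level, 16.8% were higher in both. The list's call was lost with an estimated correlation between genes (adjusted p = 0.983, or 0.929 with the block), a setting that called 0 of 10 shifted lists in simulated data. Mobp differed by 0.13 (SE 0.0263), Mbp by 0.11 (SE 0.0512), both encoding proteins of compact myelin, Mog by 0.23 (SE 0.123) and the lineage transcription factor gene Olig2 by 0.12 (SE 0.0809), each with an adjusted p of 1. The median was 0.016 within number 1 and 0.25 within number 2. Without the array titled nicotine 2 it was 0.087 and the call was lost, in a fit that takes in part of the shift between the numbers. Of the choroid plexus and ependymal genes, Ttr differed by 3.21 and Sostdc1 by 1.34 within number 2, against 0.17 and -0.017 within number 1, while Enkur and Rarres2 were at -0.28 and -0.35 within number 2 and the median of that list was 0 there. In the same arrays, the value of the 3′ probe set of Actb minus that of its 5′ probe set, a sign of RNA integrity and labelling, was 2.39 and 2.38 for titled nicotine 1 and titled saccharin 1, and 1.25 and 1.73 for titled nicotine 2 and titled saccharin 2. The same value of Gapdh was 0.092 and 0.13 in number 1 and -0.14 and 0.0070 in number 2. Tfrc, whose probe sets were near the lowest value in number 1, gives no usable value there.

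Microglia markers had a median difference of 0.062 over 21 members (camera adjusted p = 0.0251), 0.081 within number 1 and 0.069 within number 2, with 8 members higher in both numbers and 1 lower in both. The call was lost with the block (adjusted p = 0.0704), but not with the block and the filter (adjusted p = 0.0155), and it was lost with an estimated correlation (adjusted p = 0.983). The call was also lost without titled nicotine 1, without titled nicotine 2 and without titled saccharin 2, where the medians were 0.010, 0.26 and -0.053. These fits take in part of the shift between the numbers. Olfml3 differed by 0.19 (SE 0.0688), C1qc, a complement subunit gene, by 0.19 (SE 0.118), Selplg by 0.15 (SE 0.104) and the purinergic receptor gene P2ry12 by 0.62 (SE 0.502), each with an adjusted p of 1. P2ry12 was at -0.074 within number 1 and 1.31 within number 2, while Olfml3, C1qc and Selplg were higher in both. The Actb values given for the myelin list apply to these arrays as well.

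No other cell type list passed the main test, while choroid plexus (adjusted p = 0.0156) and blood markers (adjusted p = 0.0114) passed when arrays were centred. Choroid plexus markers also passed without titled nicotine 1 (adjusted p = 0.0197), and blood markers without titled nicotine 2 (adjusted p = 0.0460) and without titled saccharin 2 (adjusted p = 0.0451). The median difference was 0.022 for 20 astrocyte markers (adjusted p = 0.281), with Ntsr2 at 0.13 and Gja1 at 0.051, and -0.0099 for 28 endothelial, mural and meningeal markers (adjusted p = 0.780), with Slco1a4 at -0.35 and Abcb1a at -0.33. It was -0.014 for 27 excitatory neuron and layer markers (adjusted p = 0.587), with Rorb and Calb1 at -0.14 and -0.15, and 0.0090 for 24 inhibitory neuron markers, whose mean was -0.016 (adjusted p = 0.967), with Reln at -0.27. Among markers of tissue outside the cortex, the median was 0.00043 over 26 striatal genes (adjusted p = 0.780), with Actn2 at -0.25 and Scn4b at 0.27. The 24 thalamic and hypothalamic genes had a median of 0, a mean of -0.053 and a positive camera direction (adjusted p = 0.967), with Ptpn3 at -0.16 and Prkcd at -0.17. Over the 13 of them that reached the median level the median was -0.12. The 19 hippocampal genes had a median of -0.053 (adjusted p = 0.281, or 0.0413 with the block), 0 of them higher and 8 lower in both numbers, with Plk5 at -0.19. Only 9 of the 19 reached the median level, where 16.8% of the genes outside the myelin list were higher in both. A larger share at that level was lower in both or without a difference in a number. The hippocampal call with the block held with the filter added (median -0.15, adjusted p = 0.0462). It was lost with the block and an estimated correlation (adjusted p = 0.929), a setting that called 0 of 10 shifted lists in simulated data. Choroid plexus and ependymal markers had a median of 0.0073 over 16 members, of which 4 reached the median level (adjusted p = 0.0913). Ttr, the abundant transthyretin transcript of the choroid plexus, differed by 1.69 (SE 1.03) and Sostdc1 by 0.66 (SE 0.631). Over 12 blood markers the median was 0.015 (adjusted p = 0.142), with Lyz2 at 0.052. Centring the arrays on their medians, which adds 0.054 to every difference, turned 9 small negative list medians positive: H3K4 complexes, other chromatin modifiers, synaptic vesicles, dendrites, oxidative phosphorylation, ribosomal proteins, excitatory neurons, endothelial and hippocampal markers. In limma, 0 members of any list passed over all probe sets, and 0 passed adjusted over the list alone. With the number as a block, 1 member each of the H3K4, heat shock and endothelial lists passed adjusted over the list alone, and 0 over all probe sets. At an unadjusted p under 0.05 the axon guidance list counted 2 members, the myelin, vesicle, ribosomal and excitatory neuron lists 1 each, and the others 0.

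Sex-specific transcripts fitted the stated sex in every array. Xist, the female-specific RNA of the inactive X chromosome, stood at 12.88 ± 1.06 in titled nicotine and 12.98 ± 0.790 in titled saccharin at its brightest probe set (n = 2 each), a difference of -0.10 (SE 0.870). Eif2s3y, Uty, Kdm5d and Tsix were at the lowest value on all 4 arrays, and Ddx3y at 2.30 and 2.45. The list had a median difference of 0 over 6 members (adjusted p = 0.967).

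**Figure D2:**
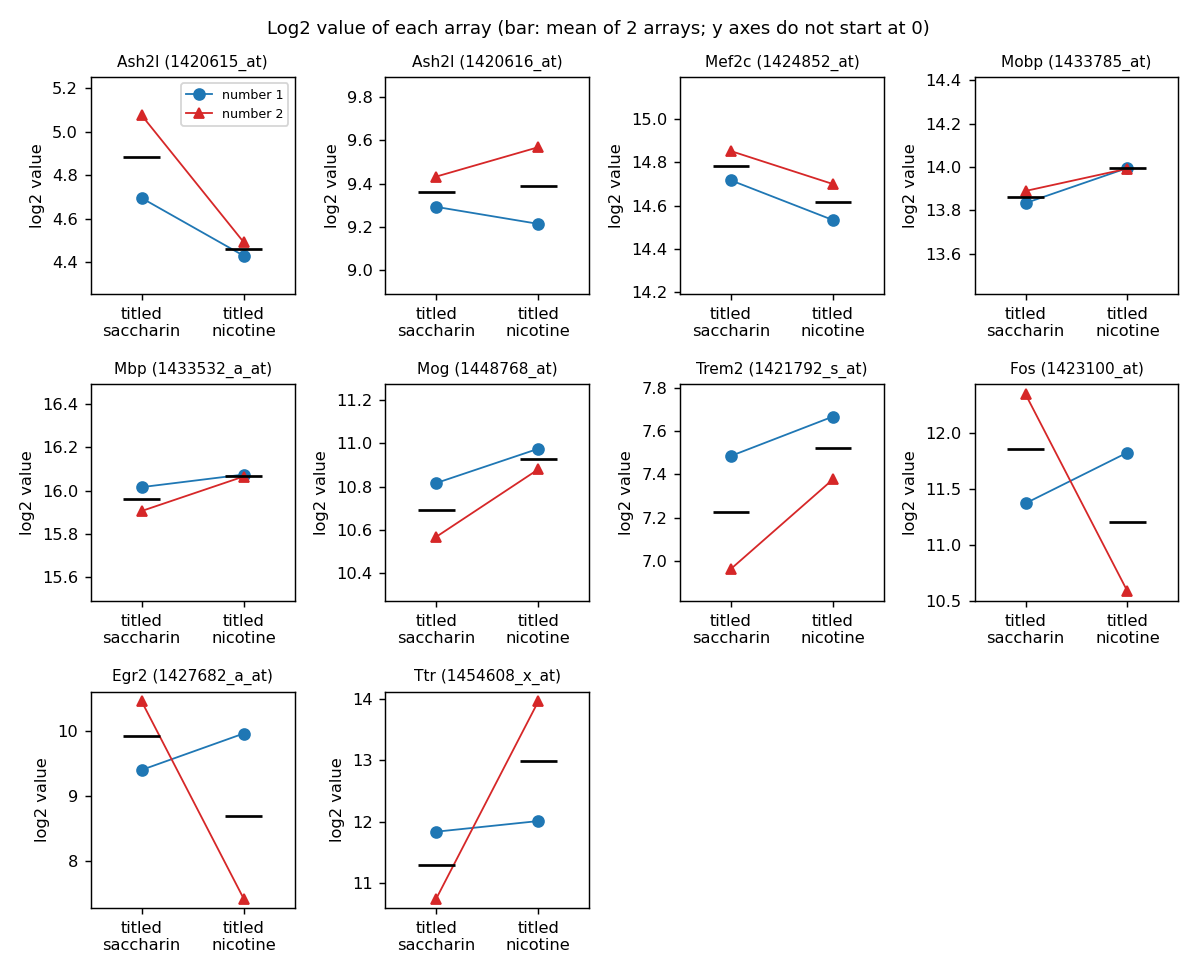
Log2 value of each array for 10 probe sets of 9 genes, titled saccharin at left and titled nicotine at right, with arrays of number 1 as blue circles, number 2 as red triangles, a line joining arrays of one number and black bars at the means of 2 arrays. The lines of both numbers slope the same way for Mobp, Mef2c and Ttr, with Ttr at 0.17 within number 1 and 3.21 within number 2. They slope opposite ways for Fos and Egr2, whose differences within number 2 were -1.77 and -3.04.

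Arrays resembled each other by number and not by title. Among probe sets at or above the median level, the log2 values of arrays that share a number correlated at r = 0.995 for number 1 and 0.980 for number 2, while arrays that share a title correlated at 0.907 for titled nicotine and 0.930 for titled saccharin. The SD of the log2 differences was 0.260 and 0.519 within numbers and 1.14 and 0.985 within titles, and 20.9% and 16.5% of these probe sets differed by more than 2-fold within a title. The shift from number 1 to number 2 in titled nicotine correlated at r = 0.857 with that in titled saccharin across probe sets, which are not independent replicates. The difference between the titles in number 1 and the same difference in number 2 correlated at r = -0.036 (Spearman's rho = -0.045), and 48.7% of probe sets had the same sign in both. When the 4 arrays were split by number, limma called 1102 of all probe sets (10051 at an unadjusted p under 0.05), and 6820 when only those at or above the median level were tested, where the split by title gave 0. Split across both, it called 0 (293 unadjusted), against 1 (347 unadjusted) by title. Xist probe sets moved in opposite directions between the numbers. In titled nicotine one went from 10.96 in number 1 to 11.99 in number 2 and another from 11.32 to 6.76, and in titled saccharin the same probe sets went from 10.72 to 13.50 and from 10.87 to 7.78.

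**Figure D3:**
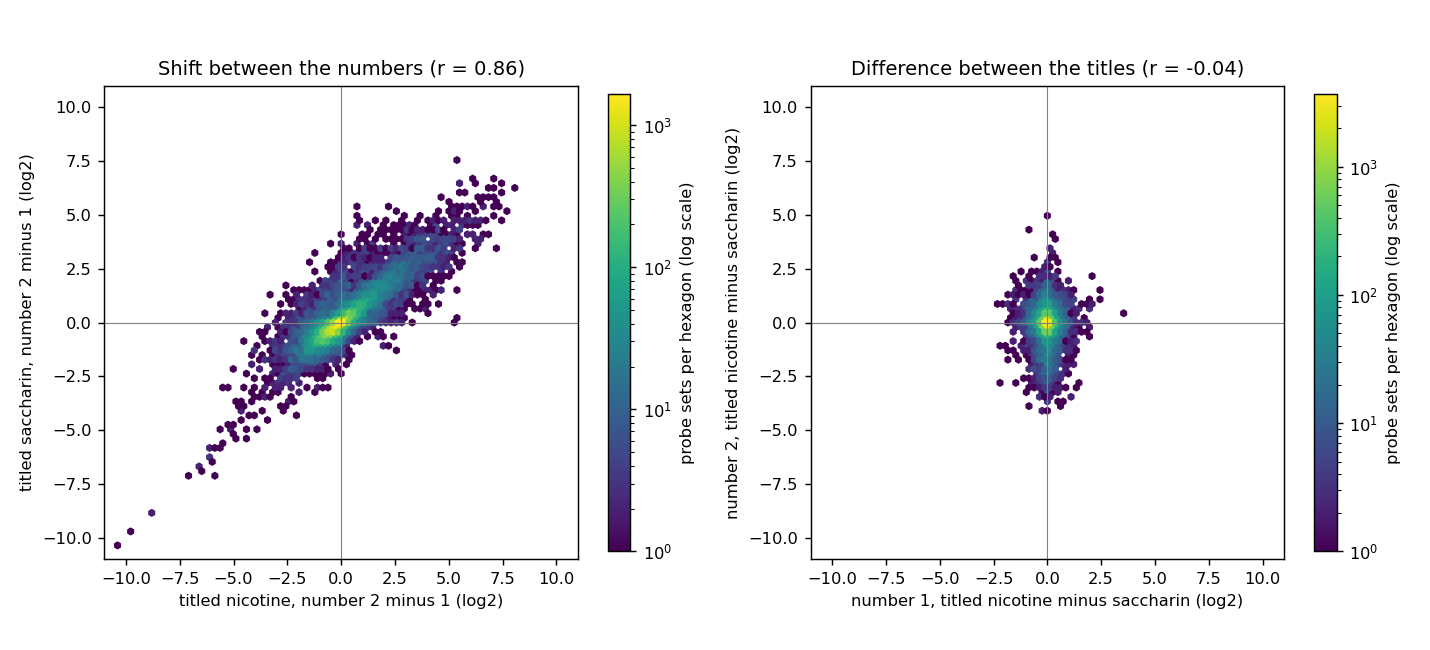
Left, the log2 shift from number 1 to number 2 of each probe set at or above the median level, titled nicotine on the x axis and titled saccharin on the y axis; right, the log2 difference between the titles, number 1 on the x axis and number 2 on the y axis, with colour giving the number of probe sets per hexagon on a log scale. The shifts lie along the diagonal (r = 0.857), and the differences between the titles do not (r = -0.036).

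The authors' deposited table of limma results listed 14 probe sets with an adjusted p under 0.05, 9 with positive and 5 with negative fold changes. All 14 had a mean level in the authors' deposited table below its median of 3.24, and 13 had an absolute log2 fold change under 0.25. Ash2l had the largest, 0.67. The smallest p in the authors' deposited table belonged to Tut4, an RNA uridylyltransferase gene listed as Zcchc11, at 0.18 (adjusted p = 0.000304), Cflar, an inhibitor of death receptor signalling, at 0.19 (adjusted p = 0.000304) and the BDNF receptor gene Ntrk2 at -0.18 (adjusted p = 0.000468). The mean levels of these probe sets there were 2.17, 2.17 and 2.16, close to the lowest mean level of any probe set, 2.14. By title the differences of these genes on the 4 arrays were -0.39, -0.059 and 0.21, each with an adjusted p of 1 in limma. For all 14 probe sets the sign in the authors' deposited table was opposite to that by title. Fold changes in the authors' deposited table correlated at r = -0.880 with the differences within number 2 and at r = -0.175 with those within number 1. The residual and prior degrees of freedom behind the authors' deposited table, worked out from its statistics, totalled 8.37, where 4 arrays leave 2 residual degrees of freedom and 5 against 5 pools leave 8.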

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

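The block with the filter, the block with the filter, trend and robust model, and the list test on the authors' statistics were chosen only after the result was seen, and the other alternatives listed above were fixed before the data were examined. The block with an estimated correlation, and the filter with an array left out, are not among those listed. The count of 1 probe set past the threshold became 0 with quantile normalization, centred arrays, the filter, the trend and robust model, the number as a block, 1 probe set per gene, the block with the filter, and that with the trend and robust model. It became 14 with the adjusted p of the authors' deposited table. The number of arrays behind those values is not given, and their degrees of freedom totalled 8.37. The change to 14 therefore need not come from processing. Leaving out 1 array gave 0 (without titled nicotine 2 or titled saccharin 2) to 379 (without titled nicotine 1), with 277 without titled saccharin 1. These fits assume that the lone array varies like the other group. They hold no block, and the lone array has only 1 of the numbers. Part of the shift between the numbers therefore enters each difference and each range below. With the filter as well, each of them gave 0. The cause was not tested for the changes in this section, apart from the sign changes with centred arrays. Another pseudocount was not run, since the values were already on a log scale.

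Of the 28 lists, 2 were called in the main setting, 5 with the block, 4 with the block and filter, 7 with centred arrays, 3 with the filter, which added heat shock (adjusted p = 0.00816), 4 with the mean of all probe sets of a gene, 0 with an estimated correlation, 0 with fry, and 2 to 5 without 1 array. The myelin median of 0.14 and the microglia median of 0.062 lost their calls with an estimated correlation (adjusted p = 0.983), and microglia, still at 0.062, with the block (adjusted p = 0.0704). fry, which asks whether a list differs from no change and not from other genes as camera does, gave an adjusted p of 0.996 for the same medians. Of the lists that the block added, glutamate and axon guidance were lost again with the filter (adjusted p = 0.287 for both). Heat shock (adjusted p = 0.00162) and hippocampal markers (adjusted p = 0.0462) held with it. Every call with the block was lost with an estimated correlation (adjusted p = 0.929). In simulated data an estimated correlation called 0 of 10 shifted lists, so its losses alone carry little information. Those data held no correlation between genes. In the fit without the block the estimated correlation was 0.0419 for myelin, 0.187 for microglia and 0.285 for heat shock, against the preset 0.01. The p-values at the preset correlation may therefore be too small, above all for microglia and heat shock.

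Centring the arrays adds the same 0.054 to every difference, which by construction turned the small negative medians of H3K4 complexes (0.046), other chromatin modifiers (0.022), synaptic vesicles (0.014), dendrites (0.052), oxidative phosphorylation (0.052), ribosomal proteins (0.043), excitatory neurons (0.039), endothelial cells (0.044) and hippocampal markers (0.00031) positive. It did the same for Mrfap1 (0.0078), Slc43a2 (0.0083), Chrna4 (0.044), Srgap3 (0.014), Map2 (0.027), Sdha (0.00039) and Rpl15 (0.00033). Quantile normalization reversed endothelial markers (0.033) and Chrna4 (0.014). The mean of all probe sets reversed synaptic vesicles (0.0014), dendrites (0.056) and endothelial markers (0.00095), and the authors' deposited table, sign turned, reversed GABA genes (-7.03e-05) and dendrites (0.0047). The brightest other probe set had the opposite sign for Fgd4 (-0.081), Wdr37 (-0.0085), Ptpn12 (-0.11), Ica1 (0.17), Eif4e (0.21), Dtwd2 (0.13), Aar2 (0.17), Ash2l (-0.43), Cxxc1 (0.45), Sv2b (0.13), Sdha (0.034), Atp5c1 (-0.26) and Hsp90ab1 (0.0080).

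Leaving out 1 array moved list medians over these ranges: H3K4 complexes -0.16 to 0.10, other chromatin modifiers -0.20 to 0.075, activity-dependent genes -0.37 to 0.084, glutamate -0.15 to 0.013, GABA -0.044 to 0.095, dendrites -0.030 to 0.0025, axon guidance -0.18 to 0.048, oxidative phosphorylation -0.038 to 0.0066, ribosomal proteins -0.039 to 0.00024, glucocorticoid -0.29 to 0.39, heat shock -0.065 to 0.20, excitatory neurons -0.090 to 0.0092, inhibitory neurons -0.15 to 0.16, myelin 0.058 to 0.17, microglia -0.053 to 0.26 and striatal -0.052 to 0.044. For named genes the ranges were Ash2l -0.15 to 0.21, Chrna4 -0.030 to 0.011, Chrnb2 -0.11 to 0.30, Chrna7 -0.28 to 0.039, Chrna5 -0.16 to 0.63, Ric3 -0.0080 to 0.35, Cdkn1a -0.27 to 1.40, Gjb6 -0.12 to 0.54, Nqo1 -0.61 to 0.058, Sostdc1 -0.019 to 1.34, Lyz2 -0.40 to 0.50, Xist -0.86 to 0.65 and Ddx3y -0.34 to 0.052.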

Other observations

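All tests of explanations in this part were chosen only after the result was seen. The split of the arrays by number may come from RNA integrity or labelling, from a difference in transcript abundance between the pools, or from both. The 3′ minus 5′ value of Actb differed between the numbers by at least 0.655 within a title and between the titles by at most 0.472 within a number. That of Gapdh was also higher in number 1 in both titles, but in titled saccharin by only 0.125, against up to 0.142 between the titles. Tfrc decides nothing, since its probe sets were near the lowest value in number 1, at 2.49 and 2.35 in titled nicotine. The control genes therefore leave RNA integrity or labelling open. A difference in abundance should move probe sets of a gene together. The shifts of the 2 brightest probe sets correlated at 0.205 across 5340 genes (95% interval 0.179 to 0.231), below a bound of 0.5 set after the result was seen. The shift of a probe set repeated between the titles at 0.857, but that compares a probe set with itself. The levels of the 2 brightest probe sets correlated at 0.730. Where both shifted by at least 2-fold, 86 genes moved the same way and 22 opposite ways. Under that bound the correlation argues against abundance as the whole cause, while these counts leave it open as a part. The 3 splits of 4 arrays are too few for a test, and the 1102 probe sets called by number against at most 1 for the others point to a structure of the samples.

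The higher myelin and microglia markers in titled nicotine may come from more oligodendrocyte RNA in those pools, from a lower share of neurons, or from 3′ bias that differed between the titles, and an effect of the exposure itself stays open and untested, as does the rise of the microglia markers. A lower share of neurons would raise astrocyte and vascular markers as well, and the myelin median exceeded theirs by 0.137 (permutation p over genes = 6.00e-05). The gap was 0.027 within number 1 (permutation p = 0.321) and 0.26 within number 2 (permutation p = 0.000170). It therefore rests on 1 pair of arrays and on genes that vary together, and leaves this open. That 13 of 26 myelin members were higher in both numbers, against 16.8% of 12180 other genes (Fisher's exact p = 9.86e-05), restates the pattern in a list singled out for it, so more oligodendrocyte RNA stays open. For 3′ bias the number 1 arrays, with nearly equal Actb values, decide little, since their myelin median was 0.016 (permutation p = 0.321), against 0.25 in number 2. These explanations cannot be told apart.

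Fold changes in the authors' deposited table may run against the titles because the exposure names were exchanged in the titles or because the contrast was saccharin minus nicotine. Both predict the correlation of -0.878 found at or above the median level, and they cannot be told apart.

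Activity-dependent and glucocorticoid-responsive genes, singled out after their values were seen, had opposite signs in the numbers. In number 1 they were higher and in number 2 lower in titled nicotine for 20 of 32 activity-dependent and 14 of 20 glucocorticoid-responsive genes, against 27.1% of 12206 genes. Fos, an immediate early gene, differed by 0.45 and -1.77, Egr2 by 0.56 and -3.04, and the glucocorticoid target Fkbp5 by 0.45 and -0.43. The cause was not tested.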
